A study of Drosophila melanogaster with 4 samples.

How the data were processed

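Chromatin from embryos of the y cn bw sp strain, aged 0 to 8 h and cross-linked in 1.8% formaldehyde for 15 min per the labels' protocols, was immunoprecipitated with an antibody against Broad or sequenced as Input. The labels give 2 ChIP and 2 Input samples, numbered 1 and 2 in each group. They do not say whether these came from separate collections of embryos. The same protocol text also describes a later egg-laying window than the stage given in the sample labels, and the stage is stated here as in the sample labels.

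The authors deposited 1 list of peaks for the 4 samples. The submitters' processing notes name CASAVA (versions 1.7.0.2 and 1.7.0.3), base-calling software, BWA, a read aligner, MACS2, a peak caller, and build BDGP5. Per the file headers, the coordinates are those of FlyBase release 5, and the file's source field reads MACS. The mapping and calling settings, the treatment of reads that map to several places, and whether the libraries were pooled before calling are not given in the sources used here. Each peak has a start, an end and a score. No name for the score is given in the sources used here. It was read as the −log10 p deposited by the authors, because 1138 of the 5171 scores (22.0%) fell on the Poisson tail probabilities of whole pileups at 1 fixed mean. The other scores are taken to have the same unit with local means, which was not tested peak by peak. A score therefore combines enrichment with depth, and a strong p does not by itself mean a large fold.

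The background mean was found by scanning means from 10 to 120 in steps of 0.01, then 0.001, for the one at which most scores equalled, at 2 decimals, −log10 of the Poisson probability of exceeding a whole pileup. On 5171 simulated scores with a known mean, the scan returned that mean, matched 100% of the peaks scored against it and wrongly matched 1.89% of the others. The simulated scores were made with the formula that the scan matches. They therefore check the scan and not the reading of the deposited scores as −log10 p. The chance share in the data was taken from 200 means drawn between 40 and 49. The number of reads per library is unknown, so no floor or interval from read counts could be given. Wilson intervals at 95% cover the counting of peaks only.

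Arm lengths of the build were not used here. The planned binomial test of peaks per arm was therefore replaced by a permutation test of counts in windows between the first and last peak of each arm. That test, the window size, the runs, the score of 50 that sets strong peaks apart and the comparisons of X and Uextra with the other sequences were chosen after the list was seen. Random placements drew midpoints uniformly between the first and last peak of an arm. The rank relation of width and score used 100000 permutations, as did the mean window counts and the widths at scores of 50 or more. The medians of window counts used 20000. The comparisons of median score and width used 10000, and their 4 p-values were adjusted together by the Benjamini-Hochberg method. On simulated data of the same size, the spacing test called 0 of 20 random lists and 20 of 20 lists in which some peaks had been moved beside another. The window test called 0 of 20 unthinned and 19 of 20 thinned sets of window counts, where thinning kept 70% of the peaks. These counts were drawn independently from the windows of the large autosome arms. They therefore do not show the rate of false calls where neighbouring windows are not independent. A simulated repeat made of complete copies, with the same sites in each, was recovered within 100 bp in 20 of 20 runs. No run without a repeat or with a weaker one was simulated, so this gives no rate of false calls. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

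Tests of peak positions against genes, of gene lists and of sequence words had also been planned at the outset, to be run only with an annotation and sequence of the build of the peaks. The gene table at hand belongs to a later release, and coordinates were not converted, so these were not run and no gene is named as bound. The rule for naming had covered br, the gene of the antibody target, the genes of the 20 peaks with the highest score, the genes with most peaks and members of the planned gene lists. With no genes, a selection of those 20 peaks is given by coordinates. The widest peaks, the longest runs and the longest gaps were added after their values had been seen. Alternatives covered the peaks kept, the window size, the neighbour distance, the joining of nearby peaks, and the omission of single arms, arm ends and the densest run.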

Results

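Binding of Broad was mapped in Drosophila melanogaster embryos aged 0 to 8 h by ChIP-seq, in which DNA cross-linked to a protein is recovered with an antibody and sequenced. Broad (Broad-Complex, gene br) is a family of BTB zinc-finger transcription factors known as early responders to the moulting hormone ecdysone, and the rabbit polyclonal antibody was raised against the core region that the isoforms share. The series held 4 samples of the y cn bw sp strain, 2 ChIP libraries and 2 Input libraries of genomic DNA, the background against which ChIP signal is read. The values used here are 1 list of peaks for the whole series, with a position and a score for each peak. No value of a single library was used here, so no statement below carries a replicate error, and every interval or p-value describes this list of peaks only. Positions are those of FlyBase release 5, and no gene annotation of that release was used here, so regions are named by coordinates and not by genes.

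The list answers where Broad signal exceeded background. It held 5171 peaks on 14 sequences, of which 4974 (96.2%) lay on the 6 chromosome arms 2L, 2R, 3L, 3R, X and 4. Arm 3R carried the most, 1230 peaks, followed by 2R with 995, 2L and 3L with 974 each, X with 727 and the small chromosome 4 with 74. A further 159 peaks lay on Uextra, the collection of unplaced scaffolds, 34 on the 5 heterochromatic Het sequences, 3 on U and 1 on the mitochondrial genome at positions 18962 to 19224. Peaks had a median width of 443 bp (quartiles 281 and 776 bp) and ranged from 201 to 5254 bp. The median width was 745.5 bp among the top 50% of peaks by score and 1091 bp among the top 25%. On the 6 arms they covered 3190 kb in all. No peaks overlapped, and the smallest gap between neighbours was 44 bp.

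The score of a peak, given by the authors, had a median of 13.85 (quartiles 10.59 and 19.61) and a range from 5.82 to 562.61. The scores were not spread evenly: 1138 of the 5171 peaks (22.0%, 95% Wilson interval 20.9 to 23.2%) carried, to 2 decimals, a value of −log10 of the probability that a Poisson count with a mean of 49.75 exceeds a whole number. The share matched by 200 other means between 40 and 49, which stands for chance, averaged 2.61% and reached 5.03% at most. Away from 49.75 itself, the next best of all means scanned, 101.49, matched 354 peaks. The score was therefore read as −log10 p, and 49.75 as a genome-wide background mean in overlapping fragments per position, the only measure of depth at hand. Peaks that matched it are called floor peaks below, since MACS scores a peak against the genome-wide mean wherever no local mean is higher.

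**Figure D1:**
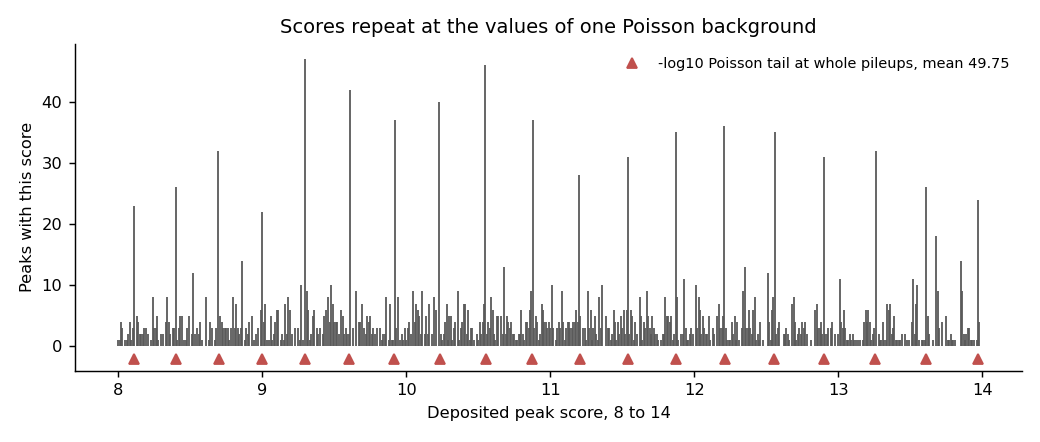
Number of peaks (vertical axis) at each deposited score from 8 to 14 (horizontal axis, 2 decimals), with triangles at the −log10 Poisson tail probabilities of successive whole pileups for a background mean of 49.75. The tall lines stand over the triangles; over the whole list, 1138 peaks sit at such values.

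Enrichment over the background mean used for scoring was modest for most peaks. Floor peaks had a median pileup of 109 fragments (quartiles 101 and 121), which is 2.19-fold the background mean (quartiles 2.03 and 2.43), and the weakest reached 1.75-fold. For any other peak, whose local background was at least as high, the same score sets an upper bound on the fold. With this bound for the other peaks, 91.0% of all peaks lay at 3-fold or less of the mean used for scoring, and the median was 2.25-fold. Floor peaks of X and of the 4 large autosome arms had medians of 2.17-fold and 2.19-fold. The local background of a floor peak may lie below the genome-wide mean, and its fold over that local background may then be higher. These medians therefore do not compare enrichment over local background between X and the autosome arms. Pileups here may be off by 1 fragment, depending on whether the caller counts the observed pileup within the tail.

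The strongest site on a chromosome arm was 3R:26075794-26081047, with a score of 210.73. It was also the widest peak of the list, at 5254 bp. The second was 3R:10198122-10200503, with a score of 200.84. A neighbouring peak at 3R:10195619-10198074, with a score of 78.81, ended just before it began. The third was 2R:14525615-14527037, with a score of 122.08, followed by 3R:23262896-23265194 at 103.29 and 3R:14973252-14974040 at 100.52. The highest peak of 3L was 3L:11012607-11015872 at 92.46, and that of 2L was 2L:19864868-19866047 at 89.12. Of the 20 arm peaks with the highest scores, 7 lay on 2L, 6 on 3R, 5 on 2R and 2 on 3L, and 0 on X or chromosome 4. The highest score on X was 67.63 and on chromosome 4 it was 32.27. A score of 50 or more was reached by 7 of 727 peaks on X (0.963%) and by 88 of 4173 on the large autosome arms (2.11%; two-sided Fisher's exact test, unadjusted p = 0.0402). Scores depend on depth, and the coverage of X relative to the autosome arms was not measured. Lower scores on X therefore need not mean weaker binding.

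Wide peaks scored higher. Across the peaks of the 6 arms, width and score had a Spearman rho of 0.773 (100000 permutations, p = 1e-05, the smallest they can give), a relation across peaks, which are not independent replicates. Both values come from the same call on the same signal, so some relation is built in. The p-value therefore does not test a property of binding. Across the 159 peaks of Uextra, rho was lower, at 0.405. After the peak on 3R, the widest were 2L:19573960-19578721 (4762 bp), 3L:5823473-5828176 (4704 bp) and 2L:6918151-6922630 (4480 bp), with scores of 56.2, 46.33 and 53.78.

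Broad peaks were sparser on X than on the large autosome arms. Over 500 kb windows between the first and last peak of each arm, X held 16.8 ± 10.3 peaks per window (SD over 43 windows) and arms 2L, 2R, 3L and 3R together 21.7 ± 11.4 (SD over 191 windows). The ratio was 0.776 (95% interval from 10000 bootstrap draws of windows, 0.633 to 0.933; two-sided permutation test of the window counts, p = 0.0114). Arm by arm, the mean was 23.6 on 2R, 22.0 on 3R, 21.5 on 2L and 19.8 on 3L. Of the 10 pairs among these 5 arms, 1 passed Benjamini-Hochberg adjustment, 2R against X (adjusted permutation p = 0.0241). The differences of X from 3R, 2L and 3L did not (adjusted permutation p = 0.0865, 0.226 and 0.33). The means of 2R and 3L differed by 3.81 peaks per window, more than those of 3L and X, at 3.00. Neighbouring windows are not independent, which makes these p-values too small and the interval of the ratio too narrow. Chromosome 4 held 6.36 ± 3.35 peaks per 100 kb (SD over 11 windows), against 4.32 ± 4.67 on the large autosome arms (SD over 963 windows), a difference that did not pass the permutation test (p = 0.119).

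**Figure D2:**
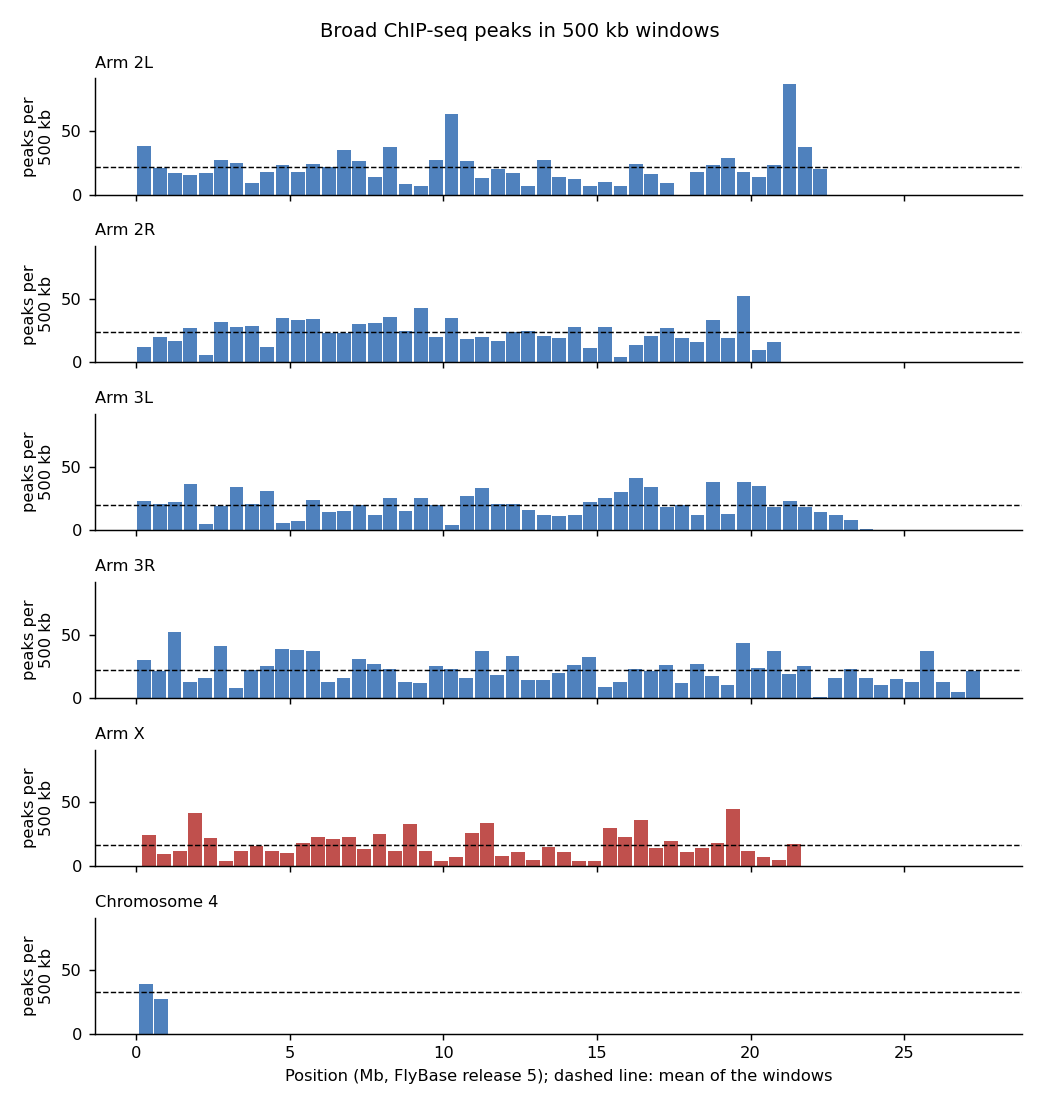
Peaks per 500 kb window (vertical axis, same scale in all panels) along each arm (horizontal axis, Mb in FlyBase release 5), with the mean of each arm's windows dashed. X (red) has a mean of 16.8 peaks per window against 21.7 on arms 2L, 2R, 3L and 3R together, and the tallest window, with 87 peaks, is on 2L.

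Peaks of X were also scored differently. On X 468 of 727 peaks were floor peaks (64.4%, 95% Wilson interval 60.8 to 67.8%), against 514 of 4173 on the large autosome arms (12.3%), a difference of 52.1 percentage points (95% interval 48.4 to 55.6; two-sided Fisher's exact test, p = 3.41e-186). Neighbouring peaks share their local background, so this p-value is far too small and the intervals are too narrow. The spread along the chromosome is the better guide. The share was high along X: in its 22 bins of 1 Mb it ran from 50.0 to 84.0%, while 94 bins with at least 10 peaks on the 4 large autosome arms had a median of 8.80%. Among those bins of 2L, 2R, 3L and 3R a share above 30% occurred 4 times, at 2L 21 to 22 Mb and 22 to 23 Mb and at 2R 0 to 1 Mb and 1 to 2 Mb. The share was 72.4% at 2R 0 to 1 Mb (21 of 29 peaks), within the range of X, 40.4% at 2R 1 to 2 Mb (19 of 47) and 48.0% at 2L 22 to 23 Mb (12 of 25). Among bins with fewer than 10 peaks, 6 of 8 were floor peaks at 3L 23 to 24 Mb and 3 of 3 at 3L 24 to 25 Mb, but 2 of 9 at 2L 17 to 18 Mb and 0 of 2 at 2R 21 to 22 Mb. At 2L 21 to 22 Mb, which holds the densest run of peaks, 65 of 124 peaks were floor peaks (52.4%), but without that run and its neighbour 6 of 36 were (16.7%). On chromosome 4 the bin at 1 to 2 Mb had 4 of 12 (33.3%) and the bin at 0 to 1 Mb 7 of 62 (11.3%). At 3R 0 to 1 Mb, 1 of 51 peaks was a floor peak (1.96%). On the Het sequences 29 of 34 peaks were floor peaks (85.3%), and on Uextra 115 of 159 (72.3%). The median score of X was 12.90, against 13.93 on the large autosome arms (two-sided permutation test of medians, adjusted p = 0.0072), and the median widths were 415 and 457 bp (adjusted permutation p = 0.0373).

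**Figure D3:**
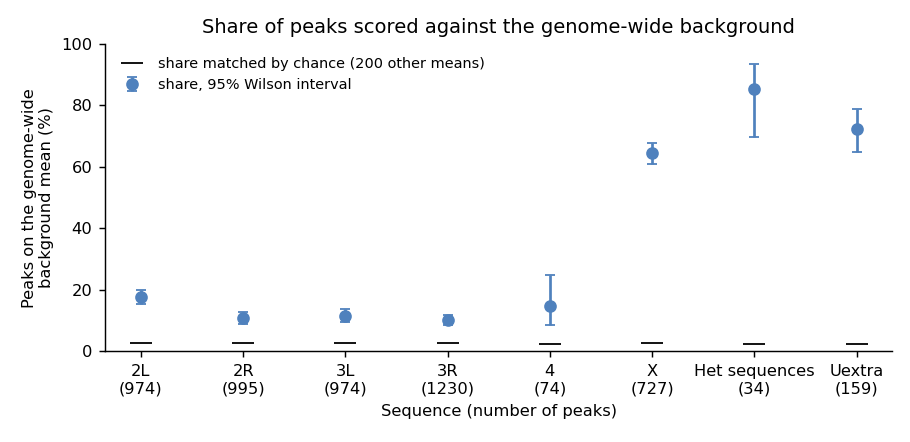
Share of peaks scored against the genome-wide background mean (vertical axis, %) for each sequence or group of sequences (horizontal axis, number of peaks in brackets), with 95% Wilson intervals, and dashes for the share that other means match by chance. X lies at 64.4%, the Het sequences at 85.3% and Uextra at 72.3%, above every large autosome arm.

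Broad peaks lay in groups along the arms. Of the 4974 arm peaks, 76.8% had another peak within 5 kb, midpoint to midpoint, while 1000 random placements within the same arms gave 34.4% on average and 36.9% at most (two-sided permutation p = 0.002, the smallest that they can give). With peaks less than 1 kb apart joined, the share was 36.0%, against 23.0% at random on average and 26.5% at most. Random placement of the listed peaks within their own 100 kb windows gave 48.7% on average. Within 1 kb the shares were 44.2% observed and 8.09% at random, and within 20 kb they were 92.8 and 81.2%. Chained at gaps of at most 5 kb, the arm peaks formed 2258 runs, 1040 of them a single peak. The 198 runs of 5 or more peaks held 1295 peaks, against a median of 41 in 100 random placements.

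The longest run, at 2L:21451410-21541559, held 72 peaks in 90.2 kb, while the longest run in the 100 random placements had 10. A second run just before it, 2L:21417309-21440713, held 16 peaks. In the 72-peak run the median score was 13.05 and the highest 26.37, and 47 peaks (65.3%) were floor peaks. Away from this region the longest runs were 2L:11987639-12011612 and 3R:2899605-2920555 with 15 peaks each and 3R:7034946-7063358 with 14. Runs of 10 peaks stood at 2R:8055805-8071865, 2R:10039523-10063350 and 3R:8248442-8260121. These had few floor peaks, 0 to 2 each. The run 3R:14738475-14754974 held 9 peaks with a highest score of 94.62, and 2R:2540779-2563640 held 9 with a highest score of 68.15. The longest stretches without a peak were 3L:23333203-24021284 (688 kb), 2L:17500563-18137434 (637 kb) and X:20382621-20905012 (522 kb).

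**Figure D4:**
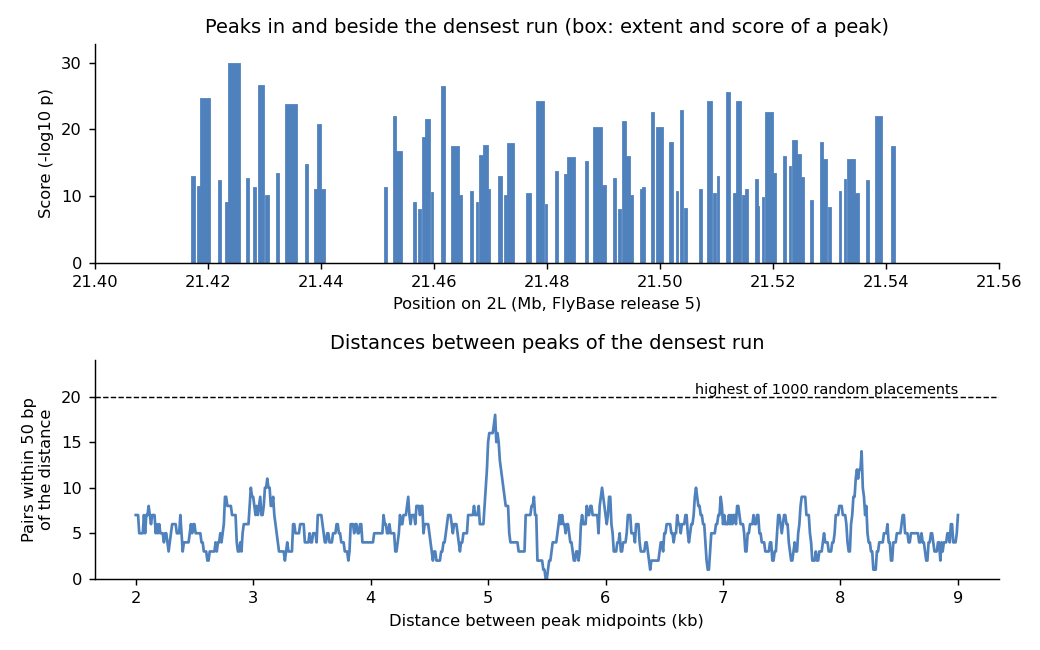
Top, extent (horizontal axis, Mb on 2L in FlyBase release 5) and score (vertical axis, −log10 p) of the peaks in and beside the densest run. Bottom, number of pairs of its peaks (vertical axis) whose midpoints lie within 50 bp of a distance (horizontal axis, kb), which is highest, at 18 pairs, at 5.06 kb; the dashed line marks the highest count in 1000 random placements, 20.

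The highest scores of the list lay outside the arms. The first 5 peaks by score were all on Uextra, led by 562.61 at Uextra 7039323 to 7039840 and 417.01 at Uextra 27346631 to 27347415, and 9 of the first 20 were. A score of 50 or more was reached by 9 of 159 Uextra peaks (5.66%, 95% Wilson interval 3.01 to 10.4%) and by 95 of 4974 arm peaks (1.91%, 1.57 to 2.33%; two-sided Fisher's exact test, unadjusted p = 0.00464). The 9 Uextra peaks are those among the first 20. Uextra and the score of 50 were chosen after the list was seen, so this test largely restates that ranking. These 9 peaks were narrow, with a median width of 432 bp and a range from 351 to 785 bp, against 1847 bp for the 95 arm peaks (two-sided permutation test of medians, p = 5e-05). Narrowness was not particular to the high scores, since no Uextra peak at any score was wider than 785 bp. Over all scores the median widths were 372 bp on Uextra and 448 bp on the arms (two-sided permutation test of medians, adjusted p = 0.0373). Over all peaks the median scores of Uextra and the arms, 14.85 and 13.78, did not differ past the threshold (adjusted permutation p = 0.0908). As a difference in mean log2 score, an alternative chosen after the list was seen, Uextra lay higher by 0.19 and passed it (two-sided permutation p = 0.0009).

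**Figure D5:**
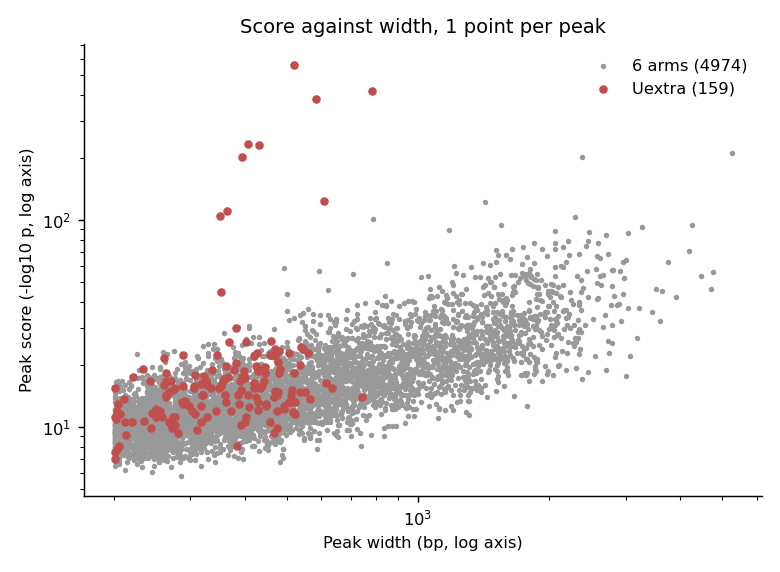
Score (vertical axis, −log10 p, log axis) against width (horizontal axis, bp, log axis), 1 point per peak, for the 6 arms (grey) and Uextra (red). The 9 Uextra peaks with scores of 50 or more have widths of 351 to 785 bp and a median of 432 bp, against a median of 1847 bp for the 95 arm peaks of such scores.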

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

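Chosen before the data were examined were the stricter score thresholds for the peak set and the top 50% for the density, the merging of touching peaks, the restriction to the 6 arms and the 1 and 20 kb distances; the others were chosen after the list was seen. The number of peaks fell from 5171 to 2596 with the top 50% of peaks by score, to 1295 with the top 25%, and to 3286 with peaks less than 1 kb apart joined, by construction in each case. The median width moved to 745.5 bp with the top 50% and 1091 bp with the top 25%. Merging touching peaks changed nothing, since no peaks touched. The ratio of X to the large autosome arms stayed below 1 and past the threshold in the 11 alternatives run. It was 0.665 with the top 50% and 0.584 with the top 25%, and lay between 0.754 and 0.798 in the others. The share of peaks with a neighbour within 5 kb was 36.0% with nearby peaks joined, still above the highest random placement, 26.5%. The observed 76.8% also exceeded random placements within the peaks' own 100 kb windows, which reached 51.4%. Joined peaks were not placed within such windows, so the joining of nearby peaks and regional density were not tested together. The excess of floor peaks on X was 51.7 to 55.6 percentage points in 3 alternatives. The higher score of Uextra, not past the threshold as a difference of medians, passed it as a difference of 0.19 in mean log2 score (permutation p = 0.0009); the cause was not tested. The densest run held 31 peaks with gaps of at most 2 kb and 33 with the top 50%. No paired analysis was possible because the list holds no value of a single library, and for the same reason no replicate was left out. The depth of each library is unknown. Alternatives for gene location, gene lists and sequence words, and for another score column, were not run.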

Other observations

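Chosen after their results had been seen were the tests of widths and of floor shares among peaks with scores of 50 or more, the shuffled gaps, and the other distances and positions tried for the densest run; the patterns themselves came from the same list.

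Fewer peaks per 500 kb were listed on X than on the large autosome arms (ratio 0.776). A few stretches of X without peaks as the whole cause are argued against, since the median window held 14 peaks on X and 21 on those arms, a difference of -7 (two-sided permutation p = 0.00315). Lower coverage of X is a candidate explanation: the local background would then more often lie below the genome-wide mean, and the share of floor peaks was higher on X by 52.1 percentage points, as predicted. With lower coverage, pileups on X would be lower while the background they are scored against stays at 49.75, so fewer sites may pass. The share of floor peaks does not test whether this lowered the number of peaks. It was also high on the Het sequences (85.3%) and on Uextra (72.3%). The labels give the sex of the embryos as unknown, and a difference in Broad binding on X was not tested and stays open.

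The densest run, 72 peaks on proximal 2L, may reflect a tandem repeat, and the histone gene cluster of that part of 2L is a candidate source from general knowledge, not from an annotation. The bound set beforehand, a period of 4.5 to 5.5 kb with more pairs than any of 1000 random placements, was missed: the commonest distance, 5.06 kb, lay in that range, but its 18 pairs stayed below the highest placement, 20. Since 10 of 1000 placements reached 18 pairs (permutation p = 0.011), missing their maximum does not exclude a repeat, and reading the outcome as undecided was itself chosen after the count was seen. The distance stayed between 4.95 and 5.06 kb in every other setting tried, with permutation p from 0.003 to 0.15 in 7 settings against random placements, 0 of which exceeded their highest placement, and from 0.001 to 0.067 in 8 settings with gaps and widths shuffled, 5 of which did; for midpoints within 50 bp, not among those 5, the highest shuffle was 18 pairs (permutation p = 0.003) but 17 in another set of 1000 draws (permutation p = 0.001). No biological explanation was tested, and the repeat stays open without a sequence of the build.

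The highest scores of the list, on Uextra, were set against repeats that are collapsed or left out in the assembly. Such repeats were predicted to raise the local background, but the share of floor peaks was higher on Uextra than on the large autosome arms by 60.0 percentage points (95% interval 52.5 to 66.4, too narrow where neighbouring peaks share a background). The prediction first named the arms, and was reworded to the large autosome arms after the shares had been seen. Against the 6 arms, at 20.0%, the share of Uextra, 72.3%, was also higher. Among scores of 50 or more, 7 of 9 Uextra peaks and 17 of 95 arm peaks were floor peaks (difference 59.9 points, 95% interval 26.2 to 77.0; two-sided Fisher's exact test, p = 0.00042). Those 7 peaks were thus scored without a raised local mean. A raised background lowers a score, so a threshold on score selects against it, and this comparison decides nothing about repeats. The share of floor peaks was also high on X (64.4%) and on the Het sequences (85.3%), so it is not particular to Uextra. The treatment of reads that map to several places is not given. If they were dropped, the local background of repeats need not rise, so these shares do not exclude such repeats. Narrow pile-ups were named only after the widths had been seen, so the difference in median width from the arm peaks, -1415 bp, restates the pattern and decides nothing. Duplicate reads and DNA of another source were not tested and stay open, and no biological explanation was tested.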
